A study of Mus musculus with 7 samples.

How the data were processed

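Cells from whole optic nerves of mice were dissociated with enzymes, freed of myelin on a magnetic column, captured on a 10x Chromium instrument and sequenced with the 3' kit, version 3.1. The 7 libraries fell into 5 groups: WT naive (2), WT 3 dpc (2), WT 7 dpc (1), sAC KO 3 dpc (1) and sAC KO 7 dpc (1), where dpc is days after a crush of both nerves. The deposited values are raw counts, the number of UMIs per gene and cell barcode in barcodes that Cell Ranger had already called as cells, against the mm10 build. Per the file headers, the counts of WT naive 1 and WT 3 dpc 1 were written by Cell Ranger 6.0.0 and those of the other 5 libraries by 7.1.0, while the submitters' notes name 7.1.0 throughout. Whether intronic reads were counted is not stated. The matrices held 53821 barcodes and 32285 genes, of which 78 share a symbol with another and were kept apart by gene ID.

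Barcodes with at least 300 genes and at most 15% mitochondrial UMIs were kept (52412). Doublets were scored per library with Scrublet, whose automatic thresholds differed widely, so the highest-scoring 0.8% per 1000 barcodes were removed instead, leaving 48652 cells. Counts were scaled per cell and log-transformed, 2000 variable genes were chosen by their rank within each library, and 30 principal components, 15 neighbours with shared-neighbour weights and Leiden clustering at resolution 1 (alternative 2) were computed over all libraries without integration, with seed 0. Clusters were named by marker lists fixed before the data were examined. A cluster took the class with the highest mean log2 ratio of marker CPM (10 CPM added) to the other clusters, if that score was at least 0.5 and 3 or more of its markers were raised by a log2 of over 1. No other class could have more markers among the 10 leading genes. Clusters with few UMIs needed at least 2 markers among those genes and at least 50% of the class's markers raised. Other clusters with no marker among the leading genes also needed at least 50% of them raised. This last limit left a cluster of 5651 barcodes, all of WT naive 2, unnamed. Clusters made up of more than 50% doublets, and clusters with more than 50 CPM of Nkx2-1, a gene of hypothalamus and pituitary, stayed unnamed. These naming limits were set after the clusters had been seen, and an alternative added the Nkx2-1 clusters to the astrocyte class. Names therefore mean cells resembling a class by markers. Of the cells kept, 34396 were named, and no cluster met the rule for oligodendrocytes.

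UMIs were summed per gene, class and library, and a class entered a comparison where each library had at least 20 cells. Astrocyte-like cells numbered 314, 610, 485, 267, 258, 590 and 403 and microglia-like cells 571, 748, 1223, 353, 2447, 700 and 2500 in the order WT naive 1, WT naive 2, WT 3 dpc 1, WT 3 dpc 2, WT 7 dpc 1, sAC KO 3 dpc 1 and sAC KO 7 dpc 1. Per library, the data held 39.5, 85.2, 128, 66.8, 132, 153 and 225 M UMIs (M for 1e6), with medians of 7672, 2248, 13395, 17772, 17613, 12781 and 17803 per barcode, in the same order. Single-library values carry exact Poisson (counts) or exact binomial (shares) 95% intervals, which cover counting error only, and a zero is given with the value that 3 counts would have.

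The 7 tested comparisons were fitted with edgeR (quasi-likelihood, TMM factors, filterByExpr, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05) on all 7 libraries, with 1 coefficient per group, or for the genotype at both days with coefficients for naive, 3 dpc, 7 dpc and genotype. A lone library was assumed to vary like the other groups. These fits had no term for the Cell Ranger version, since the labels gave none. After the headers had been read, a term for the version was added in all comparisons but WT 3 dpc against WT naive, where a fit laid down beforehand with the replicate number as a block, on 4 libraries, already matched the version. Both were tested on 3 simulations per setting of astrocyte-like data with 200 changed genes, the version term for genotype at both days. The simulated version effect was equal in all groups, so the shares of false calls hold for that case only. Fits without the term found none of the genes changed by a log2 of 1 or 2. For WT 3 dpc against WT naive these fits had 4 libraries, so the planned fit on 7 was not simulated. The block found 10.7% and 82.0% of them with 2.00% false calls where the spread followed one trend, and none where it varied between genes. The version term found 29.0% and 93.7% (3.90% false) or 2.00% and 41.7% (6.20% false). DESeq2 (Wald test, same design) was run on the same counts. sAC KO 7 dpc against WT 7 dpc was given as values only, over genes with at least 100 UMIs in the higher library and log2 ratios with 1 UMI added.

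The 27 gene lists were fixed before the data were examined, 21 tested in astrocyte-like and 12 in microglia-like cells, some in both. The lists of myelin genes and of disease-associated oligodendrocytes could not be tested without an oligodendrocyte class. The astrocyte lists were pan-reactive, neurotoxic-type (A1), protective-type (A2), homeostatic, interferon response, cholesterol synthesis, cAMP-CREB target, cAMP synthesis and breakdown, dissociation stress, proliferation, extracellular matrix and scar, secreted trophic factor, glycolysis and lactate, mitochondrially encoded respiratory, complement, antigen presentation, endoplasmic reticulum stress, and markers of myeloid cells, oligodendrocytes, vascular cells with fibroblasts, and blood. They were tested with limma's camera on voom weights with a preset correlation of 0.01 and with an estimated one, and with fry, adjusted over the lists of a comparison. For 1 library against 1, the median log2 ratio was placed among 10000 random lists matched for expression. Genes were named by a rule written before the data were examined: Adcy10; then among called genes with at least 20 CPM in the higher group, libraries that do not overlap between the groups, a plain symbol and at least 25% of the CPM of any other class, the 10 largest changes in each direction; and up to 4 members of each list with the smallest p. As the planned fits called almost nothing, the rule was applied in the same way to the fits with the block or the version term. Positions came from GENCODE vM21. A few genes that met this rule are not reported here.

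Alternatives were DESeq2, its size factors in edgeR, no low-count filter, stricter cells (1000 genes, 8% mitochondrial UMIs), doublets kept, Leiden resolution 2, each cell thinned to 2000 UMIs, each library left out in turn, only the libraries compared and 1 coefficient per group. Chosen after seeing the data were the version term, the 7.1.0 libraries alone, the Nkx2-1 clusters added, calls on the Y chromosome and near Adcy10 left out, and the fibroblast, endothelial, macrophage and mural classes as further classes. Reads were not analysed here. Versions were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.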

Results

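RNA of single cells was counted in 7 libraries from dissociated mouse optic nerves, with the 10x 3' chemistry (version 3.1) after a magnetic column had removed myelin. Uninjured wild-type nerves gave 2 libraries (WT naive 1 and 2), and wild-type nerves taken 3 days post crush (3 dpc) gave 2 more (WT 3 dpc 1 and 2). Wild-type nerves at 7 dpc gave 1 library (WT 7 dpc 1). Mice with a conditional knockout of soluble adenylyl cyclase (sAC, encoded by Adcy10) under a GFAP-driven Cre gave 1 library at 3 dpc and 1 at 7 dpc (sAC KO 3 dpc 1 and sAC KO 7 dpc 1). sAC makes cyclic AMP, a second messenger, and the series compares injured with uninjured nerves and knockout with wild-type nerves to follow how astrocytes become reactive. The libraries held between 39.5 and 225 M unique molecular identifiers (UMIs, M for 1e6) over 53821 barcodes, of which 48652 were kept as cells. The median UMIs per barcode lay between 2248 in WT naive 2 and 17803 in sAC KO 7 dpc 1. Values are counts per 1e6 UMIs (CPM) of a cell class summed per library, given as the mean ± SD for the groups of 2 libraries (n = 2), while groups of 1 library have no replicate and no error. For knockout against wild type over both days, the SD spans the 2 knockout libraries of different days or the 3 injured wild-type libraries. That SD includes differences between days and is not an error of replicates. How many mice each library pooled is not stated in the labels, and all intervals cover counting error only.

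Per the file headers, WT naive 1 and WT 3 dpc 1 were counted with Cell Ranger 6.0.0 and the other 5 libraries with 7.1.0, so that both groups of 2 libraries were split by version. Each comparison is therefore given by 2 edgeR fits. The fit fixed before the data were examined has no term for this difference. The other allows for it. In the 4 libraries of WT 3 dpc against WT naive it has a replicate block laid down beforehand as an alternative, setting libraries of 1 version against each other. In all other comparisons it has a term for the version, added after the headers had been read. Reporting changes from these fits was also decided after that. The term takes the version difference as equal in all groups, and libraries of both versions enter these fits. In astrocyte-like cells that difference was unequal: long-intron genes exceeded short-intron ones in 7.1.0 by a median log2 ratio of 2.50 in the naive pair and 1.311 at 3 dpc. Calls with the term can therefore carry part of it. The words rose and fell stand for genes past an adjusted p of 0.05 in the fit with the block or version term, and log2 fold changes are given from it with their standard error. The count of the fit without a term stands beside each. With the block or the version term 1 residual degree of freedom was left (2 for the genotype at both days), so these p-values rest largely on a spread shared by all genes.

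Injured wild-type nerves held more macrophage or monocyte-like cells than naive nerves in both pairs of libraries. Their share of kept cells was 4.07% and 3.06% in the naive libraries, 15.9% and 11.97% at 3 dpc and 12.3% at 7 dpc, and of named cells alone 5.64% and 8.57% in the naive libraries and 20.2% and 14.5% at 3 dpc. Microglia-like cells, the resident macrophages of nervous tissue, made up 14.5% and 6.38% of naive cells, 17.1% and 13.6% at 3 dpc and 38.9% (37.7 to 40.1%) at 7 dpc. Of named cells they made up 20.1% and 17.9% in the naive libraries and 21.7% and 16.5% at 3 dpc, so the pairs went opposite ways. Oligodendrocyte precursor-like cells were 0 of 3929 cells in WT naive 1, which allows a share of up to 0.094%, and 0.273% in WT naive 2. They made up 1.91% and 17.6% at 3 dpc, a difference between libraries of the same group that exceeds the gap between most groups. Astrocyte-like cells were between 4.10% (WT 7 dpc 1) and 10.3% (WT 3 dpc 2) of kept cells. Every library held at least 258 of them. T or NK-like cells reached 3.92% (3.46 to 4.43%) in WT 7 dpc 1 and 6.04% (5.57 to 6.53%) in sAC KO 7 dpc 1. In the knockout, macrophage or monocyte-like cells made up 11.3% at 3 dpc and 16.0% at 7 dpc, and microglia-like cells 9.76% and 25.5%. With finer clusters (Leiden resolution 2) macrophage or monocyte-like cells were 10.9% and 9.27% in the knockout at 3 and 7 dpc and 7.81% in WT 7 dpc 1. The higher share at 7 than at 3 dpc within the knockout thus did not hold. It depended on the naming limit: at that resolution a cluster closest to this class stayed unnamed, with a marker score of 0.287 under the required 0.5. That cluster held 674 barcodes of sAC KO 7 dpc 1, 282 of WT 7 dpc 1 and 25 of sAC KO 3 dpc 1. Intervals are exact binomial. With 2 libraries against 2, no exact test of these shares can give a two-sided p below 0.333, and dissociation and the myelin column can shift them. Of the kept cells, 10.4 to 64.3% could not be named, with the highest value in WT naive 2. No cluster met the criteria for oligodendrocytes, the myelin-forming cells.

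**Figure D1:**
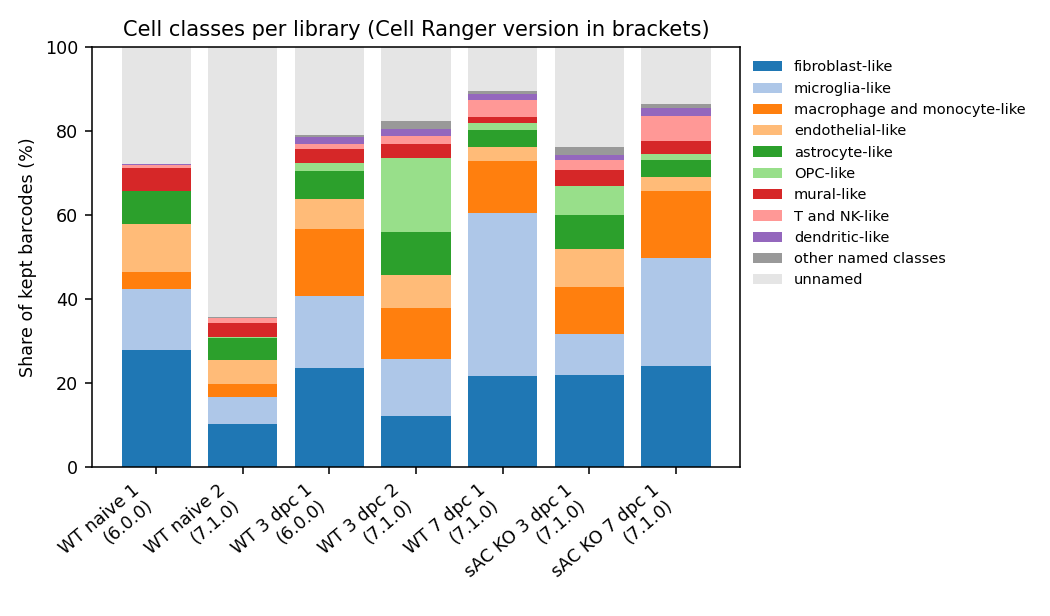
Share of kept cells (percent) that each named cell class made up in each of the 7 libraries, with unnamed cells included. Microglia-like cells reached 38.9% in WT 7 dpc 1, and 64.3% of the cells of WT naive 2 had no name.

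The targeted gene was barely detected. Adcy10 (ENSMUSG00000026567, chromosome 1, 165485183 to 165576774 in mm10) had 0 UMIs in astrocyte-like cells of both 6.0.0 libraries, where 3 counts would be 1.41 CPM in WT naive 1 and 0.296 CPM in WT 3 dpc 1. In the 7.1.0 libraries its level was 2.98 CPM (95% interval 1.54 to 5.21) in WT naive 2, 3.32 CPM (95% interval 1.77 to 5.68) in WT 3 dpc 2 and 2.27 CPM (95% interval 0.831 to 4.93) in WT 7 dpc 1. The knockout had 0.671 CPM (95% interval 0.183 to 1.72) at 3 dpc and 2.52 CPM (95% interval 1.58 to 3.81) at 7 dpc, exact Poisson intervals. At 3 dpc the knockout value lay below the interval of WT 3 dpc 2, and at 7 dpc the intervals of the genotypes overlapped. Microglia-like cells of the 7.1.0 libraries had between 0 and 0.241 CPM of it. Oligodendrocyte precursor-like cells of these libraries had between 0.867 and 9.58 CPM (the latter from 2 UMIs) and fibroblast-like cells between 0.335 and 3.05 CPM. The highest fibroblast-like value was that of WT naive 2, and the next was 0.780 CPM in sAC KO 7 dpc 1. Counts of the gene were thus not confined to astrocyte-like cells, though they were few and free RNA was not excluded. They also went with the version: over all named cells there were 2 UMIs in WT 3 dpc 1 (6.0.0) and 45 in WT 3 dpc 2 (7.1.0). Which exons the conditional allele removes is not given in the labels. Counts from a 3' kit, which may include intronic reads in the 7.1.0 libraries, do not show whether a transcript lacks exons.

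WT 3 dpc against WT naive asked how astrocytes responded to crush. Astrocyte-like cells at 3 dpc carried cell-cycle transcripts that naive cells lacked: Birc5, a regulator of cell division, was at 139 ± 13.3 CPM against 0.608 ± 0.195 CPM, and the mitotic kinase Cdk1 at 145 ± 36.2 CPM against 0.235 ± 0.333 CPM. Lcn2 and Timp1, a secreted lipocalin and an inhibitor of matrix proteases that mark reactive astrocytes, rose from 6.12 ± 8.66 CPM to 814 ± 219 CPM and from 12.8 ± 5.15 CPM to 2018 ± 378 CPM. The water channel gene Aqp1 (chromosome 6) rose from 0.360 ± 0.157 CPM to 96.4 ± 24.4 CPM, with a log2 fold change of 8.36 ± 0.64 and an adjusted p of 3.0e-35. Several genes that naive cells expressed fell. Ntsr2, a neurotensin receptor, fell by 4.08 ± 0.46 on the log2 scale, the secreted synaptic protein gene Lgi1 fell by 3.92 ± 0.41, and Adcy8, a membrane adenylyl cyclase, fell by 4.28 ± 0.47. Of 12981 genes tested with the block, 1675 rose and 1675 fell.

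By gene group, all 18 measured proliferation genes rose, among them Ube2c (284 ± 62.1 CPM against 0.249 ± 0.352 CPM), Ccnb1 (69.9 ± 8.96 CPM against 0.235 ± 0.333 CPM) and Cenpf (197 ± 11.4 CPM against 3.18 ± 1.83 CPM). Adjusted over the list alone, 18 of them passed in the fit without a block too. Of 12 genes of the protective-type (A2) reactive list, 10 rose (11 adjusted over the list alone) and 0 fell. Ptgs2, the inducible prostaglandin synthase, rose by 5.35 ± 0.47, the long pentraxin Ptx3 by 4.14 ± 0.46 and the cytokine Clcf1 by 2.59 ± 0.37 on the log2 scale. In the pan-reactive list, 6 of 12 rose (6 adjusted over the list alone), including the protease inhibitor Serpina3n (2.64 ± 0.73), the hyaluronan receptor Cd44 (1.89 ± 0.58) and the oncostatin M receptor Osmr (1.39 ± 0.41). The neurotoxic-type (A1) list had no common direction. Of its 12 genes, 2 rose (Ggta1 and Fkbp5) and 1 fell (Iigp1), and 2 and 1 did so adjusted over the list alone. Fkbp5 was at -0.19 in the fit without a block once clusters with Nkx2-1, a gene of the hypothalamus, were added to the class. By camera with a preset correlation of 0.01, the proliferation, A2 and pan-reactive lists were higher than other genes (adjusted p = 3.1e-39, 3.2e-12 and 1.6e-05). With an estimated correlation the adjusted p was 0.625 for each of the 3 with the block, and 0.375 without it. That test had 1 residual degree of freedom with the block and 2 without, so hardly any list could pass. The A1 list had an adjusted p of 0.868.

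Matrix genes moved both ways. Of 19 matrix and scar genes, 8 rose, led by the glycoprotein genes Tnc (5.64 ± 0.54) and Thbs1 (4.69 ± 0.51) and the proteoglycan gene Vcan (2.71 ± 0.38), and 2 fell. Adjusted over the list alone, 10 rose and 3 fell. Among 13 secreted trophic factors, 6 rose and 1 fell, the same numbers adjusted over the list alone. The cytokine gene Lif went from 0.844 ± 0.138 CPM to 24.7 ± 9.54 CPM and the growth factor gene Hbegf from 52.1 ± 13.5 CPM to 540.3 ± 68.8 CPM. Cholesterol synthesis genes fell in 6 of 18 cases and rose in none, both over all genes and adjusted over the list alone. Insig1, a sterol-sensing regulator, fell by 1.92 ± 0.37 and Hmgcs1, an early enzyme of the pathway, fell by 1.35 ± 0.48 on the log2 scale. Of 18 interferon-response genes 6 fell, including the antiviral gene Rsad2 (-1.40 ± 0.35), a count unchanged when adjusted over the list alone, with a camera adjusted p of 0.0975. Camera gave 0.00364 for the matrix list, 0.00352 for trophic factors and 0.00352 for cholesterol synthesis, each with adjusted p = 0.625 with an estimated correlation.

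Genes that make, break down or answer to cyclic AMP did not move together. Of 27 synthesis and breakdown genes 3 rose and 4 fell, the same counts as adjusted over the list alone. The phosphodiesterase Pde2a rose by 4.88 ± 0.48, while the membrane cyclase Adcy2 fell by 1.93 ± 0.36 and Rapgef3, a cyclic AMP-gated exchange factor, fell by 1.91 ± 0.35. Of 15 cAMP-CREB targets 3 rose (Fosb, Dusp1 and Nr4a1) and 1 fell (Ppargc1a, -2.53 ± 0.36), and 4 rose and 1 fell adjusted over the list alone. The 3 that rose are immediate-early genes and also belong to the dissociation-stress list. In that list 5 of 16 genes rose, also adjusted over the list alone (camera adjusted p = 4.6e-04, or adjusted p = 0.625 with an estimated correlation), but its median log2 ratio was -0.11 in WT 3 dpc 1 over WT naive 1 and 1.33 in WT 3 dpc 2 over WT naive 2. Without WT 3 dpc 1 the fold change of Nr4a1 in the fit without a block was -0.02. The homeostatic list had 1 gene that rose (Aldh1l1, a folate enzyme) and 2 that fell of 17, the gap junction gene Gjb6 (-2.28 ± 0.38) and the lipid receptor gene S1pr1 (-1.24 ± 0.41), and the last 2 alone passed adjusted over the list. Glycolysis and lactate genes rose in 4 and fell in 2 of 19 cases (4 and 3 adjusted over the list alone): the lactate exporter Slc16a3 rose by 2.86 ± 0.49 and the glucose transporter Slc2a1 fell by 1.21 ± 0.41. None of the 12 mitochondrially encoded respiratory genes passed with the block (median -0.15), nor adjusted over the list alone. Complement (1 of 10 rose, C1ra) and endoplasmic reticulum stress (1 of 11, Asns) gave the same counts adjusted over the list alone (complement median -0.02 and mean 0.22), and antigen presentation (1 rose and 1 fell of 15) none.

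Markers of other cells moved between the same groups. Of the 4 measured haemoglobin genes of the blood list 4 fell, also adjusted over the list alone, for example Hbb-bs from 155 ± 142 CPM to 22.0 ± 17.7 CPM (camera adjusted p = 2.9e-06, or adjusted p = 0.625 with an estimated correlation). Myeloid markers gave 2 rises (Spp1 and Lgals3) and 1 fall (Cd74) of 13, 4 and 1 adjusted over the list alone, with medians of 1.08 in the 6.0.0 pair and -1.09 in the 7.1.0 pair. In the fit without a block Cd74 turned to 0.16 with stricter cells, 0.17 at Leiden resolution 2 and 0.34 without WT naive 2. Vascular and fibroblast markers gave 5 rises and 1 fall of 11, the same adjusted over the list alone, with medians of 1.45 and -0.97 in these pairs. Oligodendrocyte markers gave 1 rise and 2 falls of 9, again the same, with medians of -0.90 and 0.75 and a camera direction (down) opposite to the median over both pairs (0.54). Spp1, an osteopontin gene that injured myeloid cells express strongly, was at 1012 ± 340.1 CPM in astrocyte-like cells and at 12118 ± 2818 CPM in microglia-like cells of the 3 dpc libraries.

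The edgeR fit without a block called 0 of 14779 genes, 1697 had an unadjusted p under 0.05, the smallest adjusted p was 0.0872, and DESeq2 called 434 (361 higher and 73 lower). Leaving out WT 3 dpc 2 gave 433 calls without a block, leaving out WT naive 1 gave 283 and leaving out WT 3 dpc 1 gave 204. Different clusters held the cells compared: cluster 36 held 97.5% of the astrocyte-like cells of WT naive 1, cluster 24 held 93.0% of those of WT naive 2, and cluster 8 held 78.6% and 88.8% at 3 dpc. The cycling cluster 39 held 18.4% and 8.24% at 3 dpc.

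**Figure D2:**
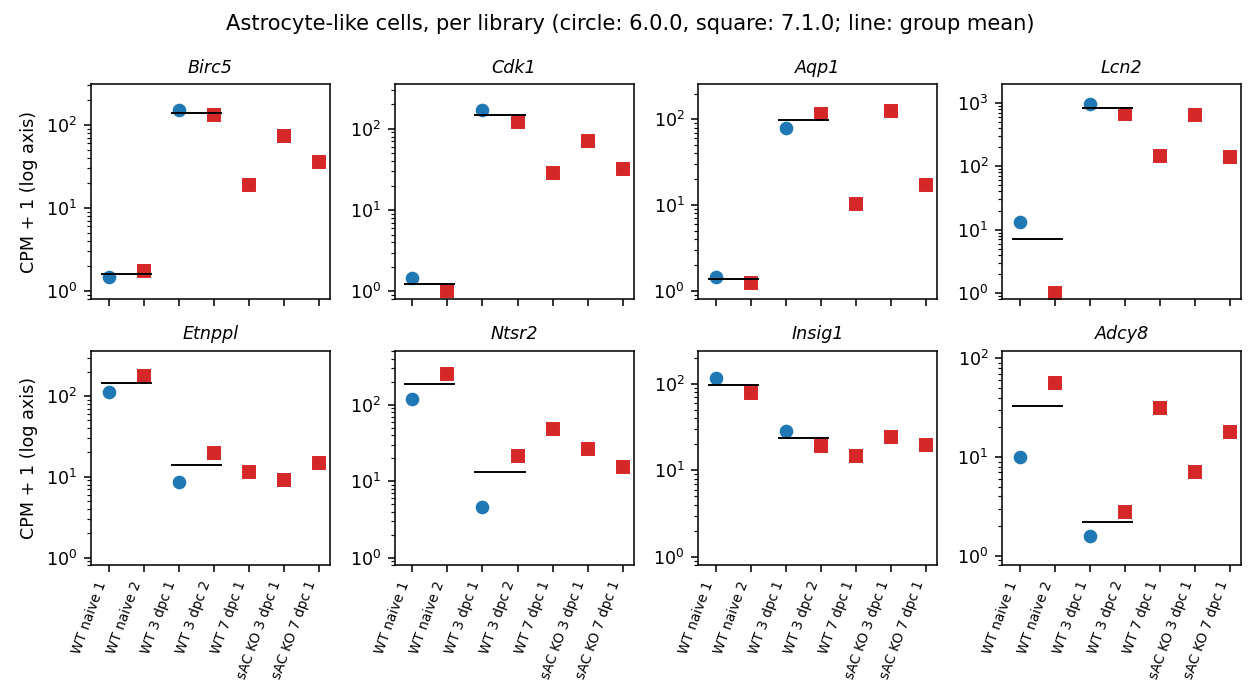
CPM plus 1 (log axis) of 8 genes in astrocyte-like cells of each library, by group; circles are libraries counted with Cell Ranger 6.0.0, squares with 7.1.0, and lines the mean of groups of 2. Birc5, Cdk1, Aqp1 and Lcn2 were higher in both WT 3 dpc libraries than in both naive ones.

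**Figure D3:**
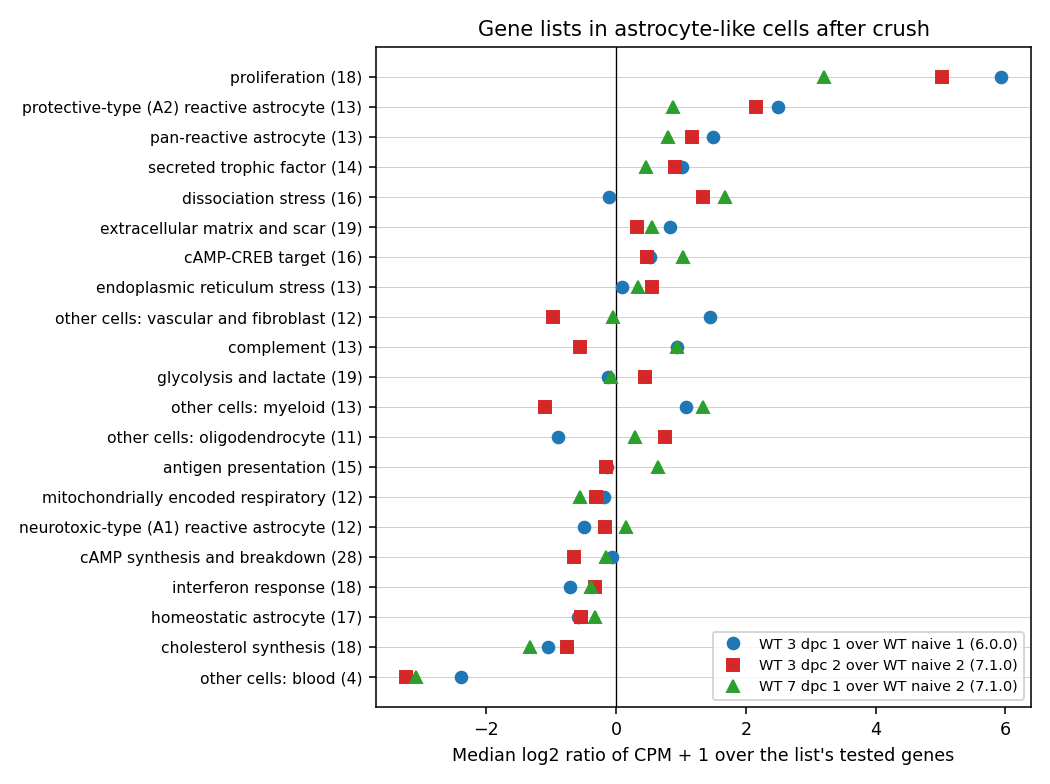
Median log2 ratio of CPM plus 1 over each list's tested genes in astrocyte-like cells, for WT 3 dpc over WT naive within each Cell Ranger version and for WT 7 dpc 1 over WT naive 2. Proliferation genes stood at 5.94 and 5.02 at 3 dpc and at 3.21 at 7 dpc.

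WT 7 dpc against WT naive asked what remained after 7 days. Cell-cycle genes were still raised in the single WT 7 dpc library: 13 of 18 proliferation genes rose and 0 fell (13 and 0 adjusted over the list alone), with Mki67, a marker of dividing cells, at 38.9 CPM against 0.746 ± 1.05 CPM. Timp1 rose by 4.96 ± 1.07 and Lcn2 by 6.19 ± 1.01 on the log2 scale. Cholesterol synthesis genes fell in 6 of 18 cases and rose in none, and 14 fell adjusted over the list alone. Idi1, an isomerase of the pathway, went from 79.6 ± 15.9 CPM to 21.5 CPM. Etnppl, an enzyme of phosphoethanolamine breakdown that resting astrocytes express, fell by 4.18 ± 0.57 on the log2 scale (adjusted p = 1.6e-10).

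In the A2 list 4 of 13 genes rose (6 adjusted over the list alone), among them Ptx3 (2.64 ± 0.59), and in the pan-reactive list 2 of 13, Timp1 and Lcn2, also adjusted over the list alone. No A1 gene passed, in either count. Matrix genes rose in 5 of 19 cases (6 adjusted over the list alone), including Tnc, Thbs1 and Vcan, and complement genes in 3 of 13 (5 adjusted over the list alone). The complement genes were C1qa, C1qb and C1qc, which myeloid cells express, and 8 of 13 myeloid markers rose with them (9 adjusted over the list alone), such as the signalling adaptor Tyrobp (2.85 ± 0.47). All 4 measured blood genes fell, also adjusted over the list alone, though Hbb-bt was at 0.26 without WT naive 2 in the fit without the term. Of 16 dissociation-stress genes 1 rose over all genes and 7 adjusted over the list alone, and their median log2 ratio to WT naive 2 was 1.67. Camera placed the proliferation (3.5e-35), cholesterol (4.1e-18), A2 (5.4e-08) and dissociation-stress (5.9e-15) lists past an adjusted p of 0.05, each with adjusted p = 0.432 with an estimated correlation. With the version term, 390 genes rose and 85 fell of 14779. The edgeR fit without it called 0, with 459 at an unadjusted p under 0.05, and DESeq2 called 46. Without WT 3 dpc 1 or WT 3 dpc 2 it called 61 or 62. The single WT 7 dpc library is assumed to vary like the other groups. Its astrocyte-like cells lay in clusters 8 (55.4%), 24 (37.6%) and 39 (5.04%).

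WT 7 dpc against WT 3 dpc asked which early changes had receded. Proliferation genes were lower at 7 dpc: 13 of 18 fell and 0 rose, and all 18 fell adjusted over the list alone, with Birc5 at 18.1 CPM against 139 ± 13.3 CPM. Genes that had risen at 3 dpc fell again, among them Aqp1 (-3.81 ± 0.59), Pde2a (-4.77 ± 0.64), Tgm1, a transglutaminase of the A2 list (-4.15 ± 0.60), and Lif (-4.23 ± 0.69), while Adcy8 (3.53 ± 0.57), Lgi1 (2.56 ± 0.49) and Syt7, a calcium sensor of vesicle release (3.08 ± 0.51), rose on the log2 scale. In the A2 list 3 of 13 genes fell (7 adjusted over the list alone) and of the trophic factors 3 of 14 (3 adjusted over the list alone), while complement (3 of 13, also adjusted over the list alone) and myeloid markers (6 of 13, also 6 adjusted over the list alone) rose together. By camera the proliferation list had an adjusted p of 2.8e-32 and the A2 list 6.7e-12, both with adjusted p = 0.698 with an estimated correlation. The version term gave 145 rises and 178 falls of 14779. Without the term edgeR called 0, 448 had an unadjusted p under 0.05 and DESeq2 called 11. Leaving out WT 3 dpc 2 gave 83.

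sAC KO against WT after crush, at both days, asked what loss of sAC did to injured astrocytes. In astrocyte-like cells Bcat1, which starts the breakdown of branched-chain amino acids, was at 379 CPM in sAC KO 3 dpc 1 and 118 in sAC KO 7 dpc 1, against 4.72 ± 1.91 CPM (SD, n = 3) in the injured wild-type libraries, and rose by 5.94 ± 0.33 on the log2 scale (adjusted p = 4.9e-05). Chil1, a chitinase-like protein secreted by reactive glia, rose by 2.59 ± 0.29, and Eif3j2, a translation initiation factor gene with a close paralog, rose by 2.57 ± 0.35. Eif3j2 was also higher in microglia-like cells, at 44.4 CPM in sAC KO 7 dpc 1 against 1.73 CPM in WT 7 dpc 1. Fcgr2b, an inhibitory antibody receptor, fell from 131 ± 31.5 CPM (SD, n = 3) to 9.76 ± 0.278 CPM (SD of the 2 days). Pcp4l1 fell from 187 ± 118 CPM to 8.98 ± 1.54 CPM. Ifi202b, an interferon-inducible DNA sensor gene, was at 78.7 and 38.3 CPM in the knockout and at 0.126 ± 0.218 CPM (SD, n = 3) in the wild type. The rest of the named genes are on the Y chromosome, Ddx3y, Uty and Eif2s3y. No member of any of the 21 lists passed over all genes, the reactive, trophic, cholesterol and cyclic AMP lists included.

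Medians of the reactive lists lay near 0 between the genotypes, and those of markers of other cells lay higher. Over all list members the median log2 fold change was 0.17 for pan-reactive, 0.23 for A2, -0.09 for A1, -0.07 for proliferation and -0.02 for cAMP-CREB target genes (camera adjusted p = 0.858, 0.159, 0.929, 0.864 and 0.929). All 18 cholesterol synthesis genes had positive values with none past the test (median 0.26, camera adjusted p = 9.9e-05, or adjusted p = 0.637 with an estimated correlation), with a median of 0.37 (17 positive) at 3 dpc and 0.06 (10 positive) at 7 dpc within the 7.1.0 libraries. Proliferation genes went opposite ways at the 2 days: their median log2 ratio was -0.50 in sAC KO 3 dpc 1 over WT 3 dpc 2 and 0.74 in sAC KO 7 dpc 1 over WT 7 dpc 1. Adjusted over the list alone, 7 oligodendrocyte markers were higher and 1 lower of 11, all 4 blood genes were higher, and endoplasmic reticulum stress, A1 and vascular lists had 1 each. The markers of vascular cells (camera adjusted p = 1.8e-10), blood (2.6e-12) and oligodendrocytes (5.5e-07) were higher in the knockout as sets, each with adjusted p = 0.603 with an estimated correlation. Their median log2 ratios in sAC KO 3 dpc 1 over WT 3 dpc 2 were 1.30, 2.45 and 1.28, with 1.28 for myeloid markers, and in sAC KO 7 dpc 1 over WT 7 dpc 1 they were 0.46, 0.59 and 0.29, with -0.29 for myeloid markers. Glycolysis (0.0107), endoplasmic reticulum stress (2.3e-05) and myeloid genes (0.0217) were higher and antigen presentation genes lower (0.0367) by camera. With an estimated correlation, on 2 residual degrees of freedom, the adjusted p was 0.850 for glycolysis and 0.603 for the others. The A1, interferon, trophic factor and both cyclic AMP lists had medians and means of opposite sign, all close to 0.

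With the version term 11 genes rose and 7 fell of 13985. The edgeR fit without the term called 0, 99 had an unadjusted p under 0.05 and DESeq2 called 17. Of the 14 called genes off the Y chromosome, 7 lie within 40 Mb of Adcy10, among them Ifi202b, Fcgr2b, Pcp4l1 and Chil1, against 2.88% of the genes tested. Bcat1 (chromosome 6) and Eif3j2 (chromosome 18) do not. Y-linked genes were expressed in the knockout libraries and nearly absent from the wild-type ones, Ddx3y at 58.4 and 73.8 CPM in the knockout against 0.466 ± 0.517 CPM in the wild type.

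**Figure D4:**
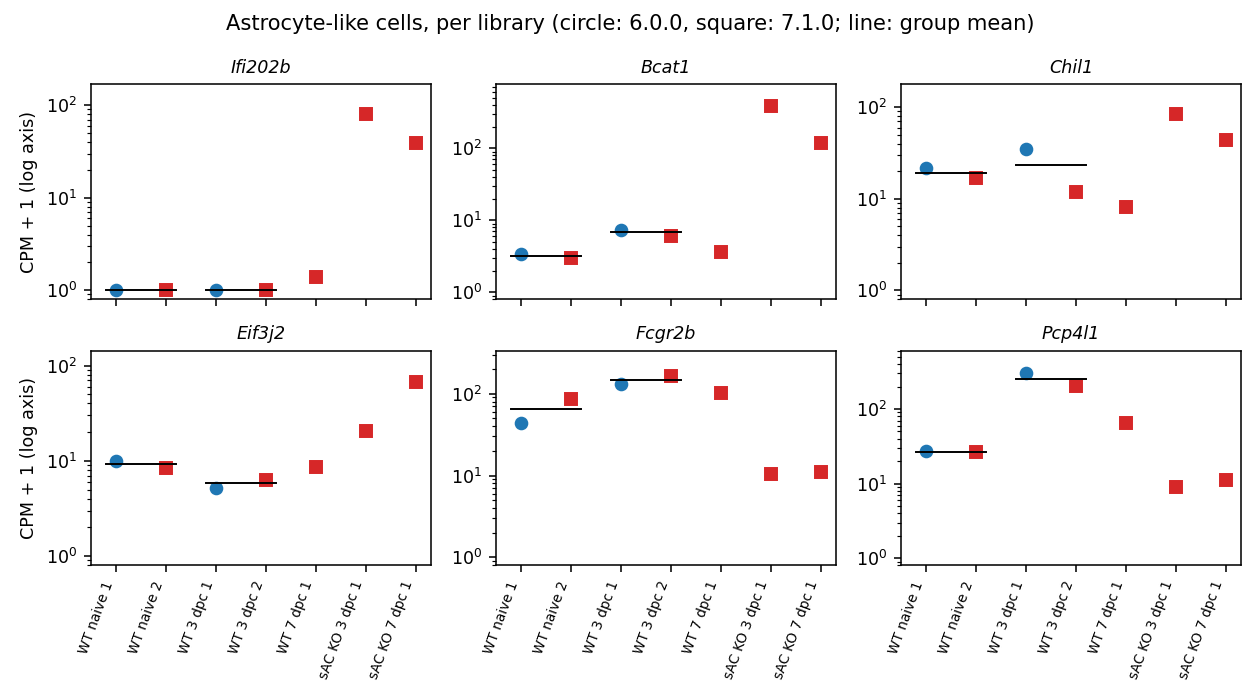
CPM plus 1 (log axis) of 6 genes in astrocyte-like cells of each library, by group; circles are libraries counted with Cell Ranger 6.0.0, squares with 7.1.0, and lines the mean of groups of 2. Both knockout libraries lay above all wild-type libraries for Bcat1, at 118 CPM or more.

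**Figure D5:**
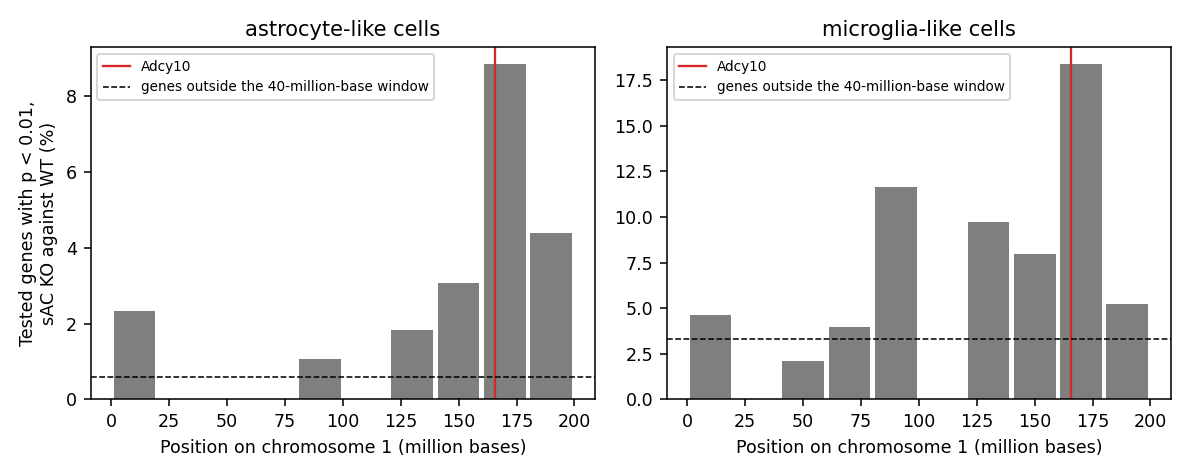
Percent of tested genes with an unadjusted p under 0.01 for sAC KO against WT after crush, in bins of 20 Mb along chromosome 1, for astrocyte-like and microglia-like cells. The red line is Adcy10 and the dashed line the percent among genes outside 40 Mb of it; the bin from 160 to 180 Mb reached 8.84% in astrocyte-like and 18.4% in microglia-like cells.

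sAC KO 3 dpc against WT 3 dpc took the early day alone. Bcat1 (379 CPM against 5.76 ± 0.917 CPM) rose, Asns, asparagine synthetase, rose by 1.99 ± 0.44, and Mndal, an interferon-inducible gene near Adcy10, fell from 64.2 ± 9.66 CPM to 5.87 CPM. All 18 proliferation genes had negative values (median -0.71) and none passed, over all genes or adjusted over the list alone. Camera gave 1.3e-11 for this list, with adjusted p = 0.585 with an estimated correlation. Oligodendrocyte markers rose in 5 of 11 cases (7 adjusted over the list alone), with the myelin junction gene Cldn11 at 21.6 CPM against 2.94 ± 0.536 CPM, as did all 4 measured blood genes, also adjusted over the list alone. Avp and Cartpt, neuropeptide genes of the hypothalamus, fell: Cartpt was at 10.1 CPM against 151 ± 95.2 CPM. With the version term 28 genes rose and 23 fell of 14779. Without it edgeR called 0, 67 had an unadjusted p under 0.05 and DESeq2 called 12. Leaving out WT 3 dpc 2 gave 30 calls, leaving out WT 3 dpc 1 gave 5 and leaving out WT naive 1 gave 3. Astrocyte-like cells of sAC KO 3 dpc 1 lay in clusters 8 (90.5%) and 39 (6.95%).

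sAC KO 7 dpc against WT 7 dpc compares 1 library with 1, so values are given without a test. In astrocyte-like cells Bcat1 was at 118 CPM (111 to 126) in the knockout and 2.64 CPM (1.06 to 5.45) in the wild type, with exact Poisson 95% intervals. The monocyte-attracting chemokine gene Ccl2 was at 43.3 CPM (39.0 to 47.9) against 6.80 CPM (4.03 to 10.7). The haem exporter gene Flvcr1 was lower, at 49.2 CPM (44.7 to 54.1) against 220.1 CPM (203 to 239), as was Trf, transferrin, at 430.2 CPM (417 to 444) against 1085 CPM (1046 to 1126). Of 7636 genes with at least 100 UMIs in the higher library, 113 were higher and 41 lower by a log2 ratio of at least 1 (74 lower with doublets kept). Proliferation genes were higher in the knockout for 18 of 18 (median log2 ratio 0.74), above nearly all of 10000 random lists of like expression. Interferon-response genes were lower (median -0.37, 3 of 18 higher, percentile 0.03), and so were A1 genes (median -0.40, percentile 0.08) and antigen presentation genes (median -0.39, percentile 0.02). Myeloid markers were lower too (median -0.29, percentile 0.02) and vascular markers higher (median 0.46, percentile 99.98). A percentile against random lists takes genes as independent and does not replace replicates. The cells lay in cluster 8 (65.3% of the knockout and 55.4% of the wild type), cluster 24 (20.8% and 37.6%) and the cycling cluster 39 (13.4% and 5.04%). In microglia-like cells 539 genes were higher and 82 lower of 11550, with a median log2 ratio of 0.17 over all of them. With TMM scaling, where that median was -0.04, the counts were 358 and 135.

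Microglia-like cells were compared in the same way as the other glia of the nerve. At 3 dpc Spp1 rose from 97.9 ± 62.1 CPM to 12118 ± 2818 CPM, the scavenger receptor gene Msr1 from 2.40 ± 1.22 CPM to 69.0 ± 30.5 CPM and the lipase gene Lpl from 49.7 ± 25.6 CPM to 681 ± 100.3 CPM. Genes of resting microglia fell: the lectin gene Siglech went from 512 ± 25.9 CPM to 87.5 ± 12.1 CPM and the purine receptor gene P2ry12 from 450.4 ± 80.6 CPM to 107 ± 37.6 CPM. Of 17 genes of the disease-associated list 9 rose and 1 fell (10 and 2 adjusted over the list alone). In the homeostatic list 8 of 13 fell and Fcrls rose, also adjusted over the list alone, and all 18 proliferation genes rose, also adjusted over the list alone. Interferon-response genes fell in 15 of 18 cases, for example Ifit3 (-2.52 ± 0.33 on the log2 scale) and the regulator Irf7 (-2.15 ± 0.31), antigen presentation genes in 6 of 15 and complement genes in 5 of 12, with the same counts adjusted over each list alone. Of 13 inflammatory cytokines 5 fell and none rose, also adjusted over the list alone. The chemokine genes Ccl3 and Ccl4 went from 9982 ± 4701 CPM to 1553 ± 242 CPM and from 24679 ± 14839 CPM to 3185 ± 303 CPM, and Tnf from 1694 ± 319 CPM to 432 ± 5.41 CPM. With them, 14 of 16 dissociation-stress genes fell, such as the heat-shock gene Hspa1b (608 ± 202 CPM to 29.8 ± 27.7 CPM) and Jun (669 ± 59.5 CPM to 132 ± 5.55 CPM), so naive microglia-like cells carried the higher level of these immediate-early and stress transcripts.

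Markers of other cells were also lower at 3 dpc in microglia-like cells. They fell in 8 of 10 oligodendrocyte genes, 7 of 8 astrocyte genes, 5 of 12 vascular genes and all 4 blood genes, and in 8, 8, 6 and 4 adjusted over each list alone, though Hbb-bt was at 0.71 with doublets kept in the fit without a block. Adjusted over the list alone, 14 dissociation-stress genes fell and 1 vascular gene rose. By camera all 12 lists passed, with adjusted p from 1.2e-34 (proliferation) and 1.0e-14 (dissociation stress) to 0.0441 (vascular). With an estimated correlation the adjusted p was 0.294 for proliferation and at most 0.311, on 1 residual degree of freedom, where hardly any list could pass. With the block 2010 genes rose and 2307 fell of 12047. Without it edgeR called 0 of 16042, 2824 had an unadjusted p under 0.05 and DESeq2 called 1094 (585 higher and 509 lower). Leaving out WT 3 dpc 2 gave 590 and leaving out WT 3 dpc 1 gave 249. With DESeq2's size factors the median of all genes in the fit without a block was -0.18 against -0.03 with TMM factors, less than the change of any gene named here. Cluster 29 held 94.8% of the microglia-like cells of WT naive 1 and cluster 26 81.5% of those of WT naive 2. Clusters 21 and 22 held 64.0% and 27.1% of WT 3 dpc 1, and clusters 5 and 22 39.7% and 38.5% of WT 3 dpc 2.

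sAC KO against WT after crush was also taken in microglia-like cells, where the GFAP-driven Cre is not meant to act. Ifi202b was at 58.3 and 50.9 CPM in the knockout and at most 0.019 CPM in the 3 injured wild-type libraries, and it was the 1 gene that passed without the version term (adjusted p = 0.00692; 485 of 14951 at an unadjusted p under 0.05; 52 by DESeq2). With the term Ifi44, an interferon-induced gene, rose to 56.2 ± 2.69 CPM (SD of the 2 days) from 0.559 ± 0.643 CPM (SD, n = 3). The lysosomal protease gene Ctse rose to 123 ± 21.9 CPM from 10.8 ± 7.41 CPM and Gatm, the first enzyme of creatine synthesis, to 598 ± 50.8 CPM from 252 ± 134 CPM. Rnaset2b, a ribonuclease gene with a close paralog, fell to 10.9 ± 9.15 CPM from 183 ± 102 CPM, Ifi204 fell by 2.15 ± 0.27 on the log2 scale, and Mpc1, a mitochondrial pyruvate carrier, fell by 1.24 ± 0.26. Of 14 complement genes 3 rose, C4b, Serping1 and Cfb, also adjusted over the list alone. Of the dissociation-stress genes Hspa1a rose (2 genes adjusted over the list alone), a direction that turned without WT 7 dpc 1 (-0.34) or without sAC KO 7 dpc 1 (-0.38) in the fit without the term. Interferon-response, antigen presentation, homeostatic, disease-associated and proliferation genes had none past the test in either count, and of the cytokines 1 was lower adjusted over the list alone. The interferon list was pooled over unlike days: its median log2 ratio was 0.96 (17 of 18 positive) in sAC KO 3 dpc 1 over WT 3 dpc 2 and -0.08 (7 of 18) in sAC KO 7 dpc 1 over WT 7 dpc 1. Markers of other cells were higher: astrocyte genes rose in 2 of 9 cases (Gfap and Sparcl1; 6 adjusted over the list alone), vascular and fibroblast genes in 5 of 12 (10), blood genes in 1 of 6 (2) and oligodendrocyte genes in 0 of 10 (1). Blood genes were higher at 3 dpc alone, with medians of 1.80 at 3 dpc and -0.73 at 7 dpc in these pairs. Camera gave 8.1e-09 for the astrocyte markers and 3.1e-14 for the vascular ones, both with adjusted p = 0.168 with an estimated correlation.

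With the version term 118 genes rose and 61 fell of 14951, and 29 of the 173 with a position off the Y chromosome lie within 40 Mb of Adcy10. The call of Ifi202b without the term was lost when any of WT 3 dpc 2, WT 7 dpc 1, sAC KO 3 dpc 1 or sAC KO 7 dpc 1 was left out (0 calls each). Clusters 5, 22 and 1 held 41.9%, 37.7% and 14.9% of the microglia-like cells of sAC KO 3 dpc 1, and clusters 1 and 5 76.3% and 19.7% of sAC KO 7 dpc 1 and 60.6% and 34.0% of WT 7 dpc 1.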

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

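The tests of the version itself, of the genes near Adcy10, of the classes in which those genes differed, of Xist, of sex over the genes highest in microglia-like cells and of the interaction with the version term were chosen only after the result was seen.

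Libraries of the same group differed along the Cell Ranger version, in a way most alike between the groups in astrocyte-like cells. The 7.1.0 over 6.0.0 log2 ratios of the naive and the 3 dpc pair were correlated there (Spearman rho = 0.78 over 12033 genes) and in microglia-like (0.686), fibroblast-like (0.537) and mural-like cells (0.426), but hardly in endothelial-like cells (0.0953). Counting of introns by 7.1.0 is a likely part of this: in astrocyte-like cells genes with the longest introns exceeded those with the shortest by a median log2 ratio of 2.50 in the naive pair and 1.311 in the 3 dpc pair, against 1.08 and 0.0454 in endothelial-like cells. Among genes without an intron the correlation was 0.405 in astrocyte-like (385 genes) and 0.329 in macrophage or monocyte-like cells, which rules out introns as the whole cause there. It was 0.130 in fibroblast-like (576 genes), 0.112 in mural-like, 0.0359 in microglia-like and -0.0078 in endothelial-like cells, so this does not extend to those classes. With astrocyte-like cells thinned to 2000 UMIs the correlation over all genes was 0.804. Random thinning leaves the expected proportions of genes in a cell unchanged, so this value does not decide on UMIs per cell. Reads and saturation were not matched. Version, day of preparation and mice cannot be told apart here.

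Genes that differed with genotype clustered around Adcy10. In astrocyte-like cells 7 of 14 called genes off the Y chromosome lay within 40 Mb of it (Fisher exact p = 4.55e-08), in microglia-like cells 29 of 173 (p = 3.9e-14), and in the latter the bin from 160 to 180 Mb held 19 calls among 174 genes tested. A segment from another mouse strain carried along with the targeted allele could produce this, since strains differ in the Ifi200 genes, and reads of these close relatives are hard to place. An effect of sAC loss confined to astrocytes was ruled out for Ifi202b, which was higher in the knockout in 5 of 5 other classes. Whether astrocytes without sAC acted on the other cells was not tested. For the other 6 called genes near Adcy10 an effect confined to astrocytes stays open. Only 2, Tnni1 and Prg4, differed the same way in another class at 25% or more of the astrocyte-like level. Prg4 (564 CPM in fibroblast-like cells, unadjusted p = 0.600) did not where it was highest. Fcgr2b (85.4 CPM in microglia-like cells) and Pcp4l1 (481 CPM in endothelial-like cells) had unadjusted p of 0.167 and 0.425 there. Mndal went the opposite way in macrophage or monocyte-like cells (0.94, unadjusted p of 0.00222). Below that level, Chil1 was also higher in microglia-like, fibroblast-like and macrophage or monocyte-like cells (2.26, 3.06 and 6.66 on the log2 scale, unadjusted p of 1.06e-04, 0.00374 and 7.14e-04), at 4.56, 8.54 and 1.83 CPM against 63.4 CPM in astrocyte-like cells, where free RNA of astrocytes was not excluded.

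Y-linked transcripts appeared in the knockout libraries, within the genotype comparisons and over all kept cells. Of the genotype calls with the version term, 4 of 18 in astrocyte-like and 5 of 179 in microglia-like cells lie on the Y chromosome. Ddx3y over all kept cells was at 60.7 CPM in sAC KO 3 dpc 1 and 80.1 CPM in sAC KO 7 dpc 1, and Xist at no more than 123.11 CPM in the knockout against 329 to 507 CPM in the wild type. Of the cells of sAC KO 3 dpc 1, 76.0% carried Y-linked transcripts without Xist and none the reverse, whereas sAC KO 7 dpc 1 held 65.5% and 17.1%, a mixture of both sexes. Wild-type libraries were female by this measure, with at most 0.563% of cells carrying Y-linked transcripts alone. Of 174 genes called in microglia-like cells off the Y chromosome, 171 kept at least 50% of their log2 ratio in the female cells of sAC KO 7 dpc 1. In astrocyte-like cells 14 of 14 did. Free RNA, however, reaches cells of both sexes. In microglia-like cells sex was therefore ruled out as the cause at 7 dpc for no more than the 9 genes that no other named class expressed more, Gatm, Mpc1 and Rnaset2b among them, of which 9 kept it. Genes were not sorted in this way in astrocyte-like cells, so the values there do not decide it.

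An interaction of genotype and day in edgeR called 8 genes in astrocyte-like and 33 in microglia-like cells with the version term and 0 in either class without it (27 and 24 at an unadjusted p under 0.05). With the term each arm rests on about 1 library, with 1 residual degree of freedom, and the knockout libraries of the 2 days differ in sex makeup, so no gene is named from it. Of the kept cells of WT naive 2, 64.3% had no name, and the pituitary hormone gene Prl was at 306 CPM over all its cells.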

How the results depend on the processing

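The comparisons rest on 2 libraries a group at most, with 1 residual degree of freedom under the replicate block, under the version term (2 for genotype at both days), in the 7.1.0 libraries alone and in several fits with a library left out, and 2 or 3 in the planned fits. Leaving WT 7 dpc 1 out of its comparisons, or sAC KO 3 dpc 1 out of sAC KO 3 dpc against WT 3 dpc, left nothing to estimate, and the comparisons of oligodendrocyte-like cells were not run because no such class was found. Shallow WT naive 1 and WT naive 2 limit what can be said of weakly expressed genes in naive cells. Except where stated, the cause was not tested.

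Calls are given in the order astrocyte-like 3 dpc against naive, 7 dpc against naive, 7 against 3 dpc, genotype at both days, genotype at 3 dpc, then microglia-like 3 dpc against naive and genotype; the planned fits gave 0, 0, 0, 0, 0, 0 and 1. DESeq2 gave 434, 46, 11, 17, 12, 1094 and 52. Without a low-count filter edgeR gave 605, 109, 0, 15, 11, 1394 and 19. Cells thinned to 2000 UMIs gave 21 in microglia-like cells for 3 dpc against naive and 6 for genotype, with Ifi202b not among the 6. With 1 coefficient per group the genotype comparison in microglia-like cells gave 0. DESeq2's size factors, stricter cells, doublets kept, Leiden resolution 2 and only the libraries compared left every count at 0 or 1, which says little of stability, because these fits could call almost nothing, and none of these settings was run with the block or the version term. At Leiden resolution 2 the share of macrophage or monocyte-like cells went from 12.3 to 7.81% in WT 7 dpc 1 and from 16.0 to 9.27% in sAC KO 7 dpc 1. Leaving out 1 library in turn gave 0 to 433, 0 to 62, 0 to 83, 0 to 0, 0 to 30, 0 to 590 and 0 to 1, and the 17 gene lists past camera ranged from 17 to 23. Of 33 lists tested over the 2 fixed comparisons, 3 passed fry and 0 passed camera with an estimated correlation. The latter had 2 residual degrees of freedom, so hardly any list could pass it.

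The replicate block, tried because WT naive and WT 3 dpc share the numbers 1 and 2, raised the calls to 3350 and 4317 in astrocyte-like and microglia-like cells. The numbers alone show no pairing in the labels, but libraries of the same number deviated together in astrocyte-like cells (Spearman rho = 0.78), hardly so in endothelial-like cells (0.0953), and shared the Cell Ranger version. The following settings were chosen after seeing the data. The version as a term gave 3254, 475, 323, 18, 51, 5019 and 179. The 7.1.0 libraries alone gave 5591, 2385, 2585, 85, 6985 and 719, without the genotype comparison at 3 dpc. With Nkx2-1 clusters added, astrocyte-like cells gave 36 for 3 dpc against naive. Without the Y chromosome and the genes near Adcy10, 7 and 144 of the genotype calls of astrocyte-like and microglia-like cells remained.

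Over 6012 values of named genes under other settings, 4615 kept direction and side of the threshold, 1375 passed it only there, 6 passed it only in the planned fit and 16 reversed, all of these past the threshold in neither. The planned fits called almost nothing, so keeping the side of the threshold mostly means passing in neither, which says little of stability. Many named genes were chosen for passing with the block or the version term, so that they passed in those fits was set in advance. Cd74 at 3 dpc against naive turned to 0.16 with stricter cells and 0.17 at Leiden resolution 2. With Nkx2-1 clusters Fkbp5 was -0.19, Igfbp7 -0.98, Mal 0.056, Nr4a1 -0.007 and Zfp36 -0.14 in this comparison, and Fosb -0.47 at 7 dpc against naive. Leaving out 1 library in turn, Cd74 ranged from -2.45 to 0.34 and Nr4a1 from -0.015 (without WT 3 dpc 1) to 2.05 at 3 dpc against naive. Avp was 0.021 at 7 against 3 dpc in the 7.1.0 libraries alone and Nppc -0.55 with thinned cells. Hbb-bt ranged from -2.66 to 0.26 (without WT naive 2) at 7 dpc against naive, and was 0.71 in microglia-like cells at 3 dpc against naive with doublets kept. Hspa1a ranged from -0.38 (without sAC KO 7 dpc 1; -0.34 without WT 7 dpc 1) to 1.98 for genotype in microglia-like cells. For sAC KO 7 dpc against WT 7 dpc, astrocyte-like cells had 74 lower genes with doublets kept (41 without), and microglia-like cells 358 higher and 135 lower with TMM scaling, against 539 and 82. With that scaling the median log2 ratio of all genes there moved from 0.17 to -0.04.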

Other observations

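The further classes were compared, and the bins along all chromosomes were tested, only after the result was seen. Log2 fold changes here are from the edgeR fit without a term, and each gene named also passed with the replicate block. Fibroblast-like cells of WT 3 dpc carried more of the smooth muscle actin gene Actg2 than those of WT naive (152 ± 31.9 CPM against 1.61 ± 0.623 CPM), and Aqp1 (6.37 ± 0.53), the surface protein gene Thy1 (5.33 ± 0.33) and Pdgfc (4.47 ± 0.34) rose too, while Kl (-3.28 ± 0.30) and Angptl1 (-3.14 ± 0.30) fell. By edgeR without a term each of these fibroblast genes had an adjusted p of 0.049, just under the threshold. Different clusters held the cells compared: cluster 10, with Actg2 among its leading genes, held 6 and 9 barcodes of the naive and 439 and 59 of the 3 dpc libraries, and cluster 11 held 7 and 9 against 392 and 91. In endothelial-like cells Fscn1 (4.20 ± 0.58) and Pdlim1 (5.09 ± 0.45) rose, and Penk (-3.74 ± 0.35) and Ndnf (31.1 ± 5.37 CPM against 212 ± 24.0 CPM) fell. In mural-like cells the cell-cycle genes Ube2c (228 ± 26.7 CPM against 0.982 ± 1.39 CPM) and Pclaf (202 ± 52.2 CPM against 0.813 ± 0.455 CPM) rose, and Cdh6 (-2.28 ± 0.35) fell. The proliferation list was not tested in this class. By edgeR without a term, 30 genes rose and 4 fell in fibroblast-like, 59 and 7 in endothelial-like and 127 and 5 in mural-like cells, while with the replicate block 1881 rose and 1882 fell, 660 and 400, and 1260 and 1212. Macrophage or monocyte-like cells had 0 calls, 1663 genes at an unadjusted p under 0.05 and 2434 calls with the block.

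Outside chromosome 1, a single bin of 20 Mb was past the threshold for genotype calls of microglia-like cells among 143 bins: the first 20 Mb of chromosome 17, with 6 calls (Afdn, Ccr6, Mpc1, Pde10a, Rnaset2b and Tagap1) among 90 genes tested (Fisher exact p = 6.2e-04, adjusted p = 0.0441). Fibroblast-like cells made up 27.8, 10.3, 23.6, 12.3, 21.8, 21.9 and 24.2% of kept cells in the order WT naive 1, WT naive 2, WT 3 dpc 1, WT 3 dpc 2, WT 7 dpc 1, sAC KO 3 dpc 1 and sAC KO 7 dpc 1. Of named cells they made up 38.5, 28.8, 29.9, 14.9, 24.3, 28.7 and 28.025%, a change largest in WT naive 2, where 64.3% of the cells had no name.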
